A study of Mus musculus with 14 samples.

How the data were processed

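Chromatin accessibility was measured by DNase-seq in livers of CD-1 (ICR) mice aged 7 weeks. Per the labels' protocols, the pituitary had been removed by the supplier in the hypophysectomized (hypox) mice, and the operation was checked through the absence of weight gain and of major urinary proteins. Hypox males received 1 intraperitoneal injection with or without recombinant rat growth hormone (GH) at 125 ng per g body weight. Livers were taken 30, 90 or 240 min after GH. The labels leave open whether the untreated hypox males received the vehicle. Fragments released by DNase I were selected by size, and those of 3 livers were pooled for each library, except 1 hypox female pool made from 2 livers. A pool is therefore the replicate, and p-values of the tests on divisions and pairings of libraries concern the spread between pools. Other p-values are from Fisher's exact tests over regions or genes.

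The 14 libraries comprised 4 of intact females, 2 of hypox females, 2 of untreated hypox males and 2 for each of the 3 times after GH in hypox males. Intact males were not analysed here. Each title carries a code. It was G92 in 10 libraries, G93 in intact female pools 3 and 4, and G103 in both untreated hypox male pools. The labels do not say what the code stands for. GH treatment and code cannot be told apart when GH-treated males are set against untreated males, nor can sex and code among untreated hypox mice. For this reason GH-treated libraries were also compared with the hypox females, which carry G92.

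Reads were aligned with Bowtie2 to the mouse build mm9, per the submitters' processing notes. Peaks were called with MACS2 2.1.0.20150731, per the file headers, without a control library, with a q cutoff of 0.05, all duplicates kept, a shift of -100 bp and an extension of 200 bp, on tags of 40 bp. The authors deposited 1 peak list per library and 1 combined list per group. Each peak carries a pileup signal, a fold enrichment over the local background and −log10 p and −log10 q values, as deposited by the authors. These describe each peak in its own library and are absent for regions without a call. The authors' fold was used only to describe and rank peaks within a class, and −log10 p only to rank and filter peaks. No counts over common regions were used, so no count model was fitted and presence of a call was compared, as the design had provided for peak lists.

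Depth was 13078268 to 33700120 tags per library, per the file headers, and lists held 17691 to 35851 peaks. Lists thus differed in depth and length, and absence of a call means that a region was not detected at that depth and threshold, not that it was closed. The reference was the mouse assembly of the same build with GENCODE vM1. All peaks lay on its chromosomes, and 0 reached past a chromosome end. Peaks of the 14 lists on autosomes and X that shared at least 1 bp were merged into 48148 regions, with a median width of 498 bp. A region counted as called in a library when a peak of that library overlapped it. Regions were placed by their summit, with a promoter defined as 1000 bp on either side of a transcription start. Coordinates are 1-based in mm9.

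For each comparison, a region was specific to one side when every library of that side called it and no library of the other side did. The total of such regions was set against all other divisions of the same libraries into groups of the same sizes, by exact enumeration and one-sided. For all 6 GH libraries against the 4 hypox libraries the planned statistic was the count of GH-only regions, and the total is given beside it. A chance model gave a further reference. In it, the chance of a call depended only on how many of the 14 libraries called the region and on the length of each library's list. Similarity was the Jaccard index of called regions, tested over all ways of pairing the 10 libraries with code G92. Shared regions of time points were set beside the chance model, a value for independent lists, and a version with separate controls. The value for independent lists was the product of the list sizes over 37152, a number below that of all 48148 regions.

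Short consensus sequences were searched on both strands in 200 bp around the summit. They were those of STAT5 (TTCNNNGAA), HNF6/CUX, HNF4A, a direct repeat of nuclear receptor sites, HNF1, C/EBP, FOXA, the glucocorticoid receptor, AP-1, CTCF, NF-Y, ETS and the AGGTCA hexamer, with STAT5 variants holding 2 or 4 bases in the gap as controls. Shares were compared by two-sided Fisher's exact test with regions called in all 14 libraries, matched on width in bins of 100 bp and on GC in bins of 5%. Benjamini-Hochberg adjustment was over 15 sequences. Matching kept 55.1 to 98.9% of a class. Regions are not replicates of animals, so these p-values describe regions of these libraries only.

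A gene was linked to a region in its body or within 10 kb upstream. The 13 gene lists were direct GH/STAT5 targets, male-biased and female-biased liver genes, shared hepatocyte genes, thyroid-responsive, glucocorticoid-responsive, circadian and ubiquitous genes, and markers of Kupffer cells, endothelial cells, stellate cells, cholangiocytes and lymphocytes. Of 155 names, 151 matched the annotation directly and 4 through RefSeq synonyms of GRCm38.p6. Each list was tested by two-sided Fisher's exact test against other protein-coding genes with a region called in every library of either side, adjusted over 13 lists. Several families, among them Mup, Cyp2b, Cyp2c, Cyp3a and Cyp4a, hold near-identical copies, so a missing call there is no evidence of closed chromatin.

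The groups, comparisons, lists, consensus sequences and alternatives were set before the data were examined. The named regions were also set by rule: per comparison and direction, the 10 specific regions with the highest mean fold, and each gene of the lists with a specific region, up to 30 genes. Regions named outside that rule are said to have been chosen after their values were seen. The comparison of 30 and 90 min together with the 4 hypox libraries was added after seeing the data, as were the classes by time and by sex. Alternatives included lists of equal length, −log10 p of at least 10, coverage of at least 50% of a region, the combined lists, and each library left out in turn. Divisions within pool numbers or codes were added after seeing the data.

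The procedures were tested on simulated data. Of 200 changed regions, 73.2% were recovered in calls drawn for GH 30 min against hypox males, where 73.1% was the value expected from the drawn call rates, and 43.3% for all 6 GH libraries against the 4 hypox libraries. With no change, 0 of 20 draws passed the split test for all 6 GH libraries. With change, 20 of 20 passed for all 6 GH libraries, whereas 2 libraries against 2 cannot pass with or without change. Calls were drawn independently for each library, so the draws do not show the error rate where pools of a group are alike. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, pysam 0.24.0, samtools 1.23.1 and matplotlib 3.10.9.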

Results

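DNase-seq profiles of mouse liver were compared to ask how removal of the pituitary and 1 pulse of GH change accessible chromatin. GH acts on the liver largely through the transcription factor STAT5. The 14 libraries gave 48148 regions, of which 7423 were called in every library and 10897 in 1 library. Promoters made up 35.1% of the regions called in all 14 libraries and 24.96% of all regions. Libraries held 13078268 tags (intact female pool 3) to 33700120 tags (hypox male pool 2), and lists held 17691 to 35851 peaks. Fold values below are the authors' peak enrichments, given as mean ± SD over the libraries of the side that called the region.

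The sex labels were matched by the Y chromosome. Peaks on Y numbered 1 to 3 in the 6 female libraries and 63 to 91 in the 8 male libraries. Of the 14 shared hepatocyte genes, 13 had a linked region in some library and 11 had a region called in all 14. All 10 ubiquitous genes and all 12 circadian genes had a linked region, and 7 and 8 of them respectively had one in all 14 libraries. Among markers of other cells, 7 of 8 endothelial, 5 of 8 stellate, 3 of 8 lymphocyte, 2 of 8 Kupffer and 2 of 6 cholangiocyte genes had a region in any library. None of the 8 lymphocyte genes had a region shared by all libraries of any group. The male-biased Mup1, Mup7, Cyp4a12a and Cyp4a12b and the female-biased Cyp2c40, Cyp2c69, Cyp3a41a and Cyp3a41b had no region, which in these families of near-identical copies is no evidence of closed chromatin. The male-biased Cspg5, Elovl3 and Moxd1 had none either.

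On average, pools of the same group shared more regions than pools of different groups. Within the 10 libraries of code G92, the mean Jaccard index was 0.671 for the 5 same-group pairs and 0.621 for the others (5 of all pairings as high, exact one-sided p = 0.00529). The pools of 30 min and of 90 min were as alike across the times (mean 0.703, 4 pairs) as within them (0.706 and 0.713). The 240 min pools shared less with each other (0.63) than with untreated males (0.653), 30 min (0.634) or 90 min (0.637). The hypox female pools likewise shared 0.615 with each other and 0.616 to 0.657 with the male groups. Hypox male pools were the most alike (0.729). Intact female pool 3 had a mean index of 0.433 against 0.539 to 0.624 for the 13 other libraries, and a promoter share of 17.28% against 27.92 to 45.57%. Among the 4 intact pools, neither gap passed Dixon's test (gap over range 0.616 and 0.618), nor did any of 11 measures. The plot of overlaps shows these values for all pairs.

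**Figure D1:**
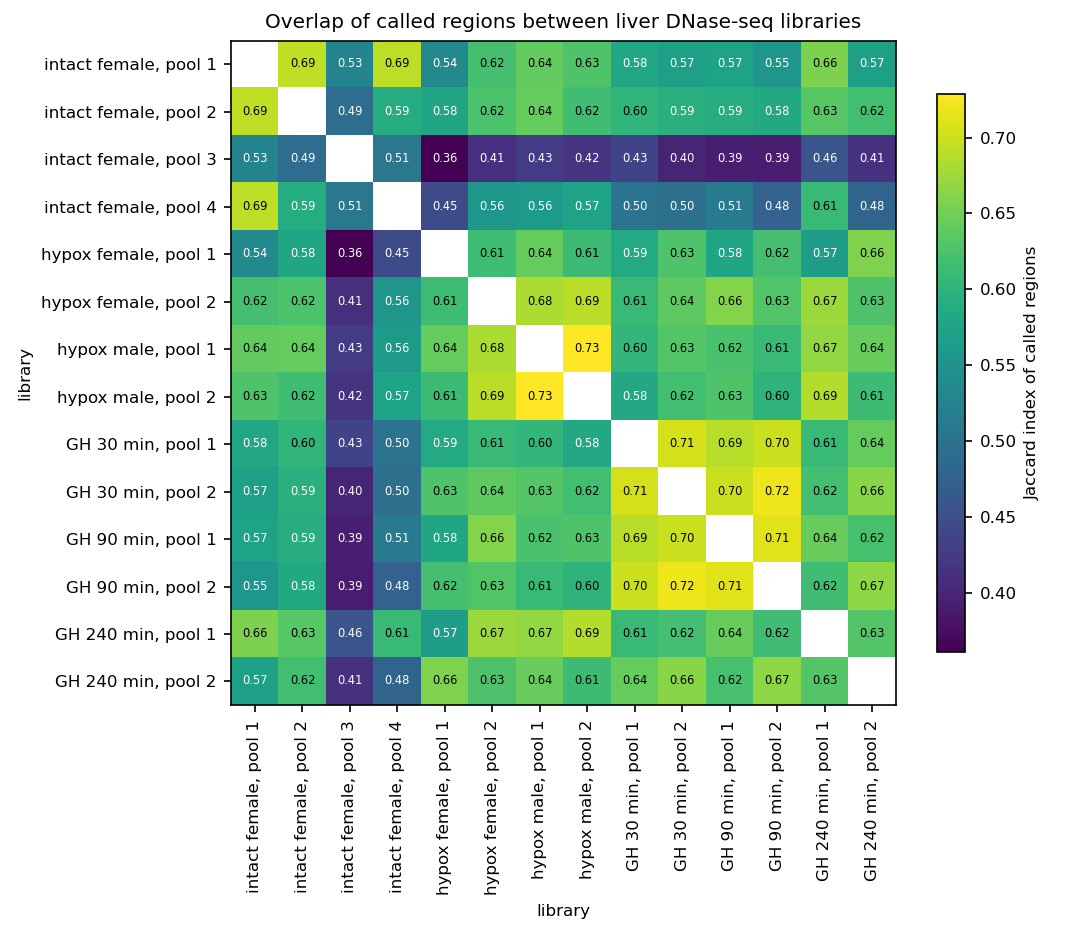
Jaccard index of called regions (color, no unit) for each pair of the 14 libraries, named by group and pool on both axes. The 30 and 90 min pools form a block around 0.70, and intact female pool 3 has the lowest values.

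The first comparison asked which regions differed between females with and without the pituitary. Regions at genes of female-biased expression were among those called in all 4 intact and no hypox library. They included introns of the cytochromes Cyp3a44 (chromosome 5: 146611768-146612241, mm9, fold 8.21 ± 2.53, SD, n = 4) and Cyp3a16 (5: 146215267-146215857, 9.89 ± 0.6). Cux2, which encodes a female-specific repressor of male-biased genes in mouse liver, had an intronic region (5: 122448792-122449301, 6.39 ± 1.42). Cyp17a1, a steroid 17-hydroxylase, had 1 located 2.9 kb upstream (19: 46750158-46750685, 4.75 ± 0.27). These 4 regions were called in no male library. A1bg, with a region 4.7 kb upstream (15: 60757235-60757762, 12.17 ± 2.02), and Prom1, with 2 intronic regions, completed 6 of the 20 female-biased genes tested. The background share was 10.03% (odds ratio 4.02, exact p = 0.0115, adjusted p = 0.15 over 13 lists). The exact test passed without intact pool 2 (adjusted p = 0.014), without intact pool 3 (0.0452) or without hypox pool 1 (0.0121).

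Among direct GH/STAT5 targets, 2 of 10 genes had an intact-only region. These were Socs2, a feedback inhibitor of GH signalling, in an intron (10: 94871130-94871760, 6.52 ± 0.81) and the repressor gene Bcl6 (16: 23979479-23979924, 4.48 ± 0.54). Neither region held the STAT consensus. The Socs2 region was called in no male library, with or without GH. The Bcl6 region was called in 1 untreated hypox male pool and in males at each time after GH. Male-biased genes gave 3 of 15, with Cyp7b1, an oxysterol hydroxylase, holding 2 intronic regions. Beside these, endothelial markers gave 2 of 4, Stab2 and Pecam1 (adjusted p = 0.344, Fisher's exact test). The stellate marker Reln, the only 1 tested, had an intact-only intronic region and a hypox-only promoter region (5: 21850228-21850954, 4.32 ± 1.0, n = 2). Glucocorticoid-responsive genes gave 2 of 10 (Fkbp5 and Pck1), thyroid-responsive genes 1 of 4 (Me1), circadian genes 1 of 12 (Clock) and ubiquitous genes 1 of 9 (Actb). No list passed the adjusted threshold in either direction.

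The highest intact-only folds were in introns of Tex14 (11: 87284999-87285314, 15.97 ± 2.23) and Ptprm (17: 67508773-67509360, 15.93 ± 3.23). A region 36.0 kb downstream of the start of Igf2, a fetal growth factor gene, held the STAT consensus (7: 149816509-149817049, 14.83 ± 2.81). It was called in no untreated hypox male library and in all 6 GH libraries. Hypox-only regions were led by 1 located 62.3 kb upstream of Eea1 (10: 95340646-95341359, 11.61 ± 0.98, n = 2) and 1 in an intron of Wwox (8: 117189439-117190111, 11.31 ± 0.5). The region 6.0 kb upstream of Epor, the erythropoietin receptor gene, was called in both hypox females and all 8 male libraries (9: 21773669-21774419, 10.66 ± 2.99).

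In all, 1978 regions were intact-only and 286 hypox-only, against 551 and 41 in the chance model. Promoters were 5.7% of intact-only regions (exact 95% interval 4.7 to 6.8) and 30.1% of hypox-only regions (24.8 to 35.7). The total of 2264 exceeded those of the 14 other divisions (highest 1590), with exact one-sided p = 0.0667, the smallest that 15 divisions allow. With lists of equal length the counts were 1192 and 923, and within code G92 2848 and 639. Leaving out a library can only raise such counts. Intact-only regions numbered 3627 without intact pool 2 and 4419 without hypox pool 2. Hypox-only regions numbered 526 without intact pool 4, 2302 without hypox pool 1 and 624 without hypox pool 2. Without hypox pool 1 the intact-only regions, at 2248, were thus the fewer.

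**Figure D2:**
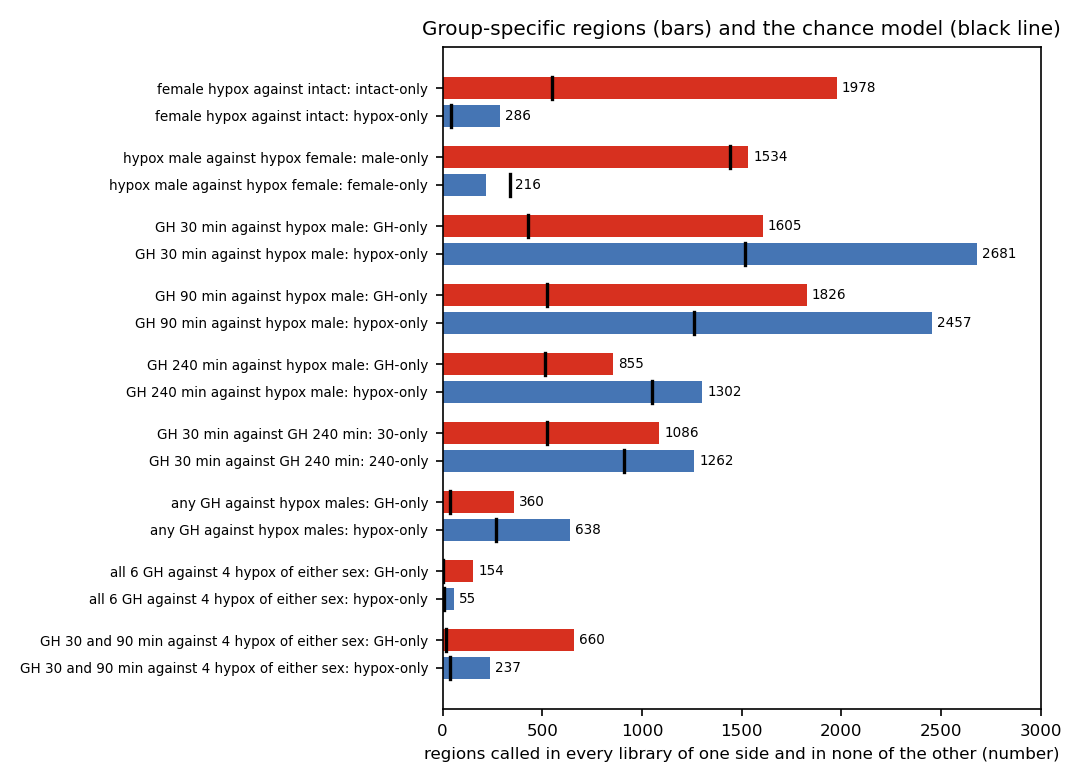
Number of regions called in every library of one side and none of the other, for both sides of each comparison (red and blue bars), with the chance model as a black line. Of the 18 counts, 17 lay above the chance model, and female-only regions lay below it (216 against 336).

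Sex differences among untreated hypox mice were compared next, with sex and library code confounded. Male-only regions included introns of Cyp7b1 (3: 18039766-18040246, 4.45 ± 0.96, n = 2) and Gstp1, a glutathione transferase gene (19: 4036357-4036698, 3.39 ± 0.05). These were 2 of the 14 male-biased genes tested. The 2 named regions were each called in 3 of the 14 libraries, both untreated hypox male pools and 1 pool of 240 min after GH. Most male libraries thus lacked them, as did all female libraries. Female-biased genes gave 2 of 17 (Cyp2b10 and Cyp4a10) and endothelial markers 2 of 6 (Clec4g and Tek), against a background of 9.2%, each with adjusted p = 1.0 by Fisher's exact test. A region 14.1 kb upstream of Akr1c21, a hydroxysteroid dehydrogenase gene, was called in all 8 male and no female library (13: 4559048-4559340, 9.56 ± 1.13). The highest female-only fold was on X within the long noncoding RNA gene 6720401G13Rik, named Firre in RefSeq (X: 47964603-47965586, 14.68 ± 0.11). The counts were 1534 male-only and 216 female-only regions, against 1442 and 336 in the chance model. With 3 divisions the smallest exact p is 0.333, and another division gave 1582 against the real total of 1750. With lists of equal length the counts were 751 and 489, and female-only regions with −log10 p of at least 10 numbered 123. Male-only regions numbered 4308 and 3115 without hypox male pool 1 or 2 and 5032 without hypox female pool 2. Female-only regions numbered 378 and 734 without hypox male pool 1 or 2, and 3290 and 597 without hypox female pool 1 or 2. Without hypox female pool 1 the male-only regions, at 1962, were the fewer.

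Across all libraries, 8 regions were called in all 6 female and no male library and 6 in all 8 male and no female library, against 0.7 and 0.05 in the chance model. This division was chosen after the data were seen. All 8 female-only regions lay on X, 7 of them within 6720401G13Rik (X: 47908921-47988498, minus strand), a gene known to escape X inactivation. Of the 6 male-only regions, 3 lay on X. The total of 14 was reached by 28 of 3003 divisions of the libraries (exact one-sided p = 0.00932). The map of this locus shows the calls per library.

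**Figure D3:**
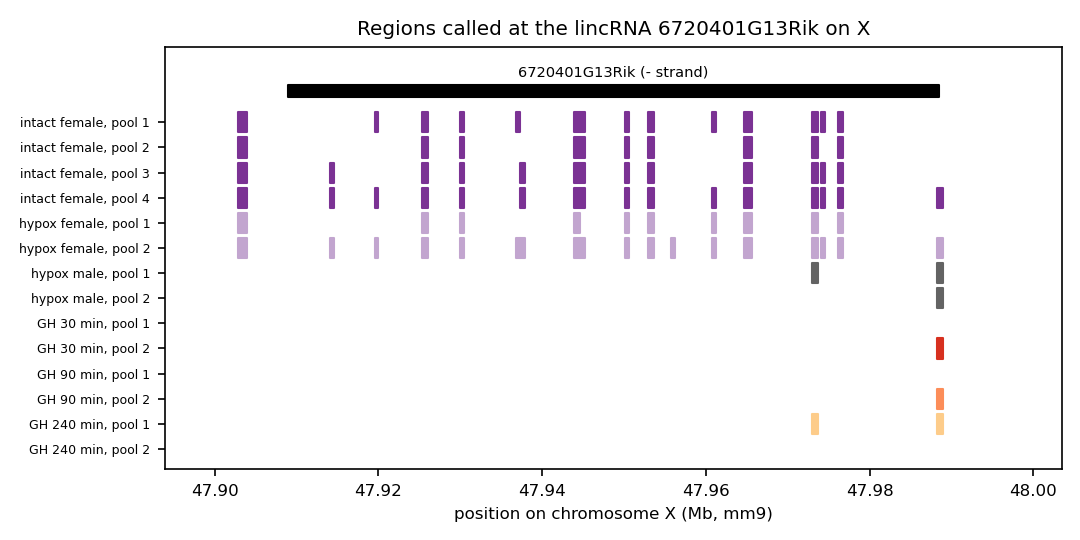
Regions called in each library (bars, short regions drawn at a minimum width) along chromosome X (Mb, mm9) around 6720401G13Rik (black bar), colored by group. Most regions within the gene were called in female libraries only.

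The response to GH was examined first at 30 min. Known GH targets were among the regions called after GH. Socs2 had 2 regions that both 30 min pools called and both untreated hypox male pools lacked. They lay 0.8 kb upstream of its start (10: 94880353-94880802, 6.99 ± 1.47, n = 2) and in its untranslated region (10: 94848202-94848738, 5.21 ± 0.78). Igf1, which encodes the main hepatic mediator of GH action, had 3 intronic regions, with the highest fold at 10: 87336221-87336705 (5.64 ± 0.76). Bcl6 had an intronic region (16: 23981112-23981743, 6.88 ± 0.39) and 1 located 7.7 kb upstream (16: 23996425-23996880, 4.39 ± 0.37). Of these 7 regions, 6 held the STAT consensus. The 3 genes were 3 of the 10 direct targets (exact p = 0.0469, adjusted p = 0.305).

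Beyond these targets, the highest fold at 30 min was 4.4 kb upstream of Ces2b, a carboxylesterase gene (8: 107350839-107351400, 19.37 ± 2.16). This region was called in no untreated library of any group. C6, a male-biased complement gene, had a promoter region (15: 4676869-4677412, 9.08 ± 3.2), and Trim24, a female-biased gene, an intronic region with the STAT consensus (6: 37863524-37864044, 8.14 ± 0.47). Both were called in all 6 GH libraries and 3 of 4 intact female libraries. Male-biased and female-biased lists each gave 2 of 16 genes with a GH-only region (adjusted p = 1.0, Fisher's exact test). Glucocorticoid-responsive genes gave 3 of 10, with 3 regions in Fkbp5 and 1 upstream of the metallothionein genes Mt1 and Mt2 (8: 96694960-96695805, 8.17 ± 0.39; exact test, adjusted p = 0.305). The liver regulator Hnf4a had an intronic region called at 30 and 90 min only (2: 163384373-163385160, 4.59 ± 1.1). Several top regions were also called in both hypox female pools, among them those at Adck5, Pex26, Itga6 and Gabbr2, so among hypox mice they were absent from the untreated males alone.

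Among the genes of the lists, hypox-only regions, called in both untreated male pools and neither 30 min pool, lay at other genes. They included the promoter of Apoa1, a main protein of high-density lipoprotein (9: 46036526-46037014, 2.96 ± 0.13), and a region downstream of Tat, a tyrosine aminotransferase gene under glucocorticoid control (8: 112523429-112524977, 5.61 ± 0.23). The Apoa1 region was also absent from both hypox female pools, which had no GH, and was called in 3 of 4 intact female pools. The Tat region was called in both hypox female pools and all 4 intact female pools. The highest fold was 1.9 kb upstream of Hrh2, the histamine H2 receptor gene (13: 54285415-54285653, 11.6 ± 4.06). Shared hepatocyte genes gave 4 of 13, endothelial markers 2 of 6 (Stab2 and Tek), stellate markers 1 of 1 (Reln), glucocorticoid-responsive genes 2 of 10 (Tat and Tsc22d3) and male-biased and female-biased genes 2 of 16 each, with adjusted p = 1.0 by Fisher's exact test. In all, 1605 regions were GH-only and 2681 hypox-only at 30 min, against 426 and 1517 in the chance model. The next division gave 814 against 4286, with a smallest exact p of 0.333. Without 30 min pool 1 the counts were 2492 and 4070, and without pool 2 3501 and 4308. Hypox-only regions numbered 6032 and 4428 without hypox male pool 1 or 2, and with lists of equal length the larger side changed, to 1777 GH-only and 1424 hypox-only regions.

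At 90 min Socs2, Bcl6 and Igf1 again had GH-only regions. Igf1 had 5 intronic regions, 4 of them with the STAT consensus. A further region 70.5 kb upstream of its start held the second-highest fold of the class (10: 87250287-87250979, 16.92 ± 0.6, n = 2). It was called in all 6 GH libraries, all 4 intact female libraries and 1 hypox female library. Pim1, a STAT-induced kinase gene, had a region 2.1 kb upstream (17: 29625300-29625947, 4.67 ± 1.78). With Socs2 and Bcl6, 4 of 10 direct targets had a GH-only region (exact p = 0.00959, adjusted p = 0.0624). By the same exact test, the adjusted p was 0.0357 without hypox male pool 2. The map of the Igf1 and Socs2 loci shows the calls in each library.

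**Figure D4:**
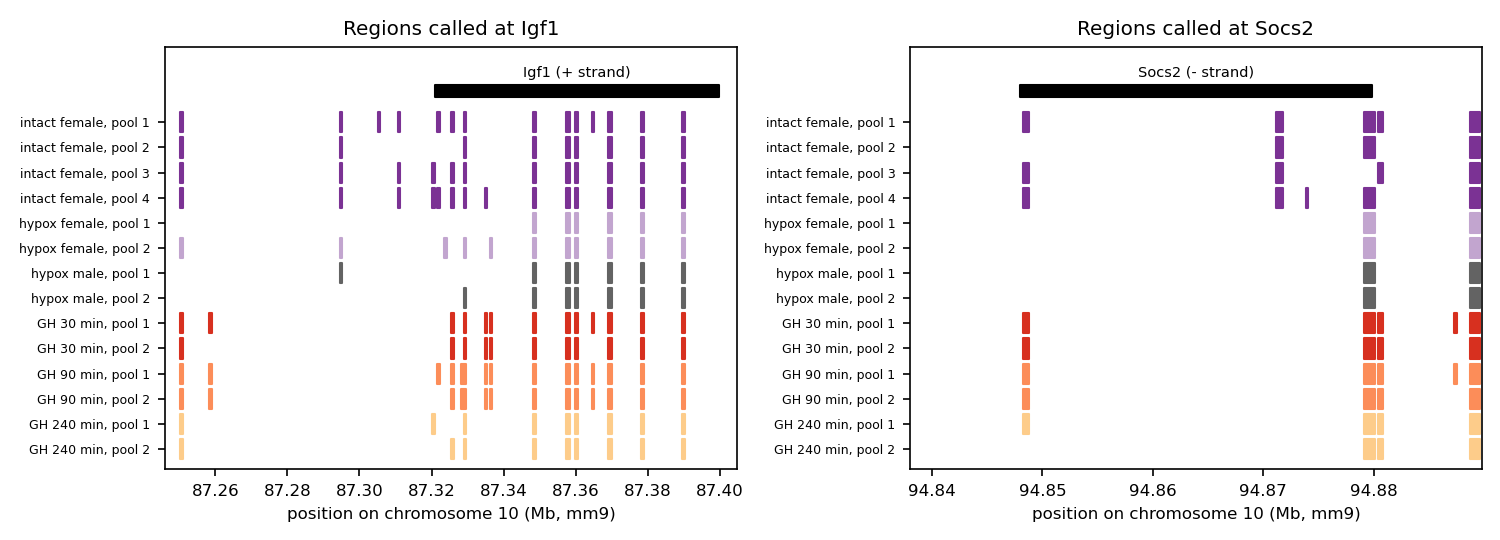
Regions called in each library (bars, short regions drawn at a minimum width) along chromosome 10 (Mb, mm9) at Igf1 and Socs2 (black bars), colored by group. The Socs2 region at 10: 94880353-94880802 was called in all 6 GH libraries and in no untreated hypox library. The Igf1 region at 10: 87336221-87336705 was called at 30 and 90 min, in neither 240 min pool and in no untreated hypox male. It was called in 1 hypox female pool.

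The Ces2b region again led the 90 min class (19.51 ± 2.18). An intronic region of Deptor, an inhibitor of mTOR signalling, was called at 30 and 90 min only (15: 55029295-55030088, 15.65 ± 0.44). C6 had a second region 8.7 kb upstream (15: 4668065-4668639, 8.33 ± 0.0). By Fisher's exact test, male-biased genes gave 3 of 16 (C6, Ugt2b38 and Wfdc21, adjusted p = 0.772), female-biased genes 2 of 15 (Trim24 and Atp6v0d2) and glucocorticoid-responsive genes 4 of 10 (Fkbp5, Mt1, Mt2 and Per1, adjusted p = 0.0624). Mt1 and Mt2 shared a single region, and the GH-only region linked to Per1 was the promoter of Vamp2, 6.8 kb upstream of Per1. In the hypox-only direction, glucocorticoid-responsive genes gave 3 of 10 (Per1, Tat and Tsc22d3, adjusted p = 0.54, exact test), so Per1 counted in both, and male-biased genes gave 2 of 16. Hypox-only regions included the Cyp17a1 promoter (19: 46747256-46747970, 3.66 ± 0.57), a region 1.2 kb upstream of Thrsp, a thyroid-responsive lipogenic gene (7: 104567098-104567635, 5.28 ± 0.63), and introns of Atf6 and of Pygl, the liver glycogen phosphorylase. The Thrsp region was called in 12 of the 14 libraries, and only the 90 min pools lacked it. The Cyp17a1 promoter was called in both 30 min pools and in neither 240 min pool. Endothelial markers gave 3 of 6 among hypox-only regions (Clec4g, Stab2 and Tek, adjusted p = 0.54, Fisher's exact test). There were 1826 GH-only and 2457 hypox-only regions, against 526 and 1261 in the chance model, and the next division gave 926 against 4283 (smallest exact p = 0.333). GH-only regions numbered 4208 without 90 min pool 2 and 2754 without hypox male pool 2. Hypox-only regions numbered 4573 without 90 min pool 1, and 5430 and 4172 without hypox male pool 1 or 2. GH-only regions were the more numerous without 90 min pool 2 (3095 hypox-only) and with equal lists (1929 against 1662).

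At 240 min no intronic region of Igf1 was GH-only. The Socs2 region 0.8 kb upstream (6.2 ± 1.57), both C6 regions (6.9 ± 1.26 at the promoter), the Trim24 intron (4.76 ± 0.34) and the Mt1 and Mt2 region (5.27 ± 0.05) were called in both pools. The Ces2b region was called in 1 pool. By Fisher's exact test, direct targets gave 2 of 10 (Socs2 and Bcl6, adjusted p = 0.538), male-biased genes 2 of 15 (C6 and Cyp7b1) and glucocorticoid-responsive genes 3 of 10 (adjusted p = 0.141). The highest fold was 33.4 kb upstream of Bicc1 (10: 70655559-70656337, 15.16 ± 1.19), in a region without the STAT consensus, and the other 9 of the top 10 held it. Dio1, the thyroid hormone deiodinase gene, had an intronic region (4: 106975233-106975820, 9.0 ± 2.18) called at 240 min but not at 30 or 90 min. Hypox-only regions included the Cyp3a25 promoter (5: 146821165-146821418, 8.07 ± 2.5) and an intron of Ppargc1a, a coactivator of gluconeogenic genes (5: 51936624-51937319, 7.47 ± 0.77). The counts were 855 GH-only and 1302 hypox-only, against 511 and 1052 in the chance model. The real total of 2157 stood against 1729 for the next division, and the smallest exact p is 0.333. GH-only regions numbered 4555 without 240 min pool 2 and 1639 without hypox male pool 2. Hypox-only regions numbered 4716 without 240 min pool 1, and 3745 and 2630 without hypox male pool 1 or 2. GH-only regions were the more numerous without 240 min pool 2 (1496 hypox-only) and with equal lists (1126 against 1035).

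The early and late times were compared directly, within 1 code. Regions called in both 30 min pools and neither 240 min pool (30-only) were led by 1 located 15.5 kb upstream of the carboxylesterase gene Ces3b (8: 107591994-107592362, 15.12 ± 4.65, n = 2). They included introns of Fcgr2b (12.93 ± 0.42) and Il1r1, the interleukin 1 receptor (12.75 ± 3.4), and Spp1, a cholangiocyte marker (5: 104865369-104866011, 9.85 ± 0.21). Both Bcl6 regions and 2 of the Igf1 introns of 30 min were absent from both 240 min pools, and another Bcl6 intronic region was 240-only. Regions called in both 240 min pools and neither 30 min pool (240-only) included introns of Cux2 (5: 122466777-122467680, 10.15 ± 2.51) and Dio1, the Cyp7b1 promoter (3: 18143443-18144003, 5.17 ± 0.85), and regions of the circadian genes Per2 and Cry2. Other groups were not part of this rule. The Spp1 region and the Cyp7b1 promoter were also called in both 90 min pools, and the Cry2 region in both untreated hypox male pools. No list passed the adjusted threshold. The counts were 1086 and 1262, against 525 and 910 in the chance model. The total of 2348 stood against 1337 for the next division (smallest exact p = 0.333), and leaving out single pools moved both counts. The 30-only regions numbered 2102 and 2761 without 30 min pool 1 or 2 and 2967 without 240 min pool 1. The 240-only regions numbered 2277 and 2241 without 30 min pool 1 or 2, 1633 without 240 min pool 1 and 6589 without 240 min pool 2. The 30-only side was thus the larger without 30 min pool 2 or 240 min pool 1, and also with equal lists (1253 against 1050).

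Calls made at 30 and 90 min overlapped. Of 1605 and 1826 GH-only regions, 1120 were shared, against 93 in the chance model and 78.9 for independent lists. With the untreated males as control at one time and the hypox females at the other, 660 were shared, against 73.7 for independent lists. By construction these are the regions called at 30 and 90 min and in no untreated hypox library. Hypox-only regions shared 1529, against 570 and 177.3, and 237 with separate controls, against 61.7 for independent lists. The 2 untreated male libraries were not divided between the times, since each time would keep 1 control library, so part of the excess may come from shared controls. Of the 360 GH-only regions common to all 6 GH libraries against untreated males, the highest folds lay 12.4 kb upstream of Pex26 (15.37 ± 2.49, n = 6) and near Bicc1 (15.36 ± 1.18). The 10 highest folds (12.98 to 15.37) all exceeded 12.87, the highest among those of the 360 that no untreated hypox female pool called. These 10 regions were thus each called in at least 1 hypox female pool. Among the 360, Fkbp5, Mt1 and Mt2 made up 3 of 10 glucocorticoid-responsive genes against a background of 2.03%. This was the only 1 of 234 list tests to pass (exact p = 0.000923, adjusted p = 0.012). A single region served both Mt1 and Mt2. This region and the Fkbp5 region were each also called in 1 hypox female pool, so neither was absent from the untreated hypox mice of both sexes. The list call ended without 240 min pool 2 (adjusted p = 0.0552, exact test) and when 2 kb upstream were searched (0.189). Direct GH targets passed without hypox male pool 2 (adjusted p = 0.0305, exact test). The 360 GH-only and 638 hypox-only regions gave the largest total of 28 divisions (998 against 616, exact one-sided p = 0.0357, the smallest possible). GH-only regions numbered 607 without 240 min pool 2 and 631 without hypox male pool 2, and hypox-only regions 1259 without 240 min pool 1, and 2413 and 1650 without hypox male pool 1 or 2. With equal lists the larger side changed, to 413 GH-only and 388 hypox-only regions.

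The strictest class required a call in all 6 GH libraries and in none of the 4 untreated hypox libraries of either sex. It held 154 regions, with 55 in the opposite direction, against 4 and 9 in the chance model. Among the 10 highest folds were regions 3.5 kb upstream of Acsm2 (7: 126693938-126694701, 12.19 ± 2.03, SD, n = 6), in an intron of the sterol carrier gene Scp2 (4: 107796478-107797059, 11.27 ± 1.96), 11.6 kb upstream of the liver regulator Cebpa (7: 35892455-35893107, 11.26 ± 4.04) and 12.0 kb downstream of the start of Cish, a STAT5-induced suppressor of cytokine signalling (9: 107210104-107211341, 11.22 ± 0.93). Of these 10, 9 held the STAT consensus. The Socs2, C6 and Trim24 regions also belonged to this class. In the opposite class were an intron of Ppargc1a (6.62 ± 1.53, n = 4), the Cyp2a12 promoter (7: 27813795-27814228, 5.7 ± 1.1), an intron of the endothelial gene Stab2 (10: 86342966-86343536, 5.68 ± 0.83) and the Reln promoter (4.13 ± 0.62). No other of the 210 divisions gave as many as 154 regions (highest 101, exact one-sided p = 0.00476). By the total of 209, 3 divisions were as large (exact one-sided p = 0.0143). The highest, 415, set the 4 libraries of 30 and 90 min apart from the 240 min and untreated hypox libraries, a structure of the samples by time. Among the 28 divisions that keep the number of libraries of each code per side, 154 was again the highest count (next 101, exact one-sided p = 0.0357, the smallest possible), but another total was as large (215, exact one-sided p = 0.0714). The count was 289 without 240 min pool 2 and 338 without hypox female pool 2, and in the opposite direction 165 without 240 min pool 1, 90 without hypox male pool 1, and 243 and 96 without hypox female pool 1 or 2. The opposite direction was the larger without hypox female pool 1 (156 against 243) and with the combined lists (731 against 840).

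When the 4 libraries of 30 and 90 min were set against the 4 untreated hypox libraries, a comparison added after the data were seen, 660 regions were GH-only and 237 hypox-only, against 19 and 37 in the chance model. Ces2b led (19.44 ± 1.77, n = 4), followed by a promoter region within Madd, 22.9 kb downstream of a start of the gene (2: 91000740-91001615, 15.67 ± 0.75). Socs2, Igf1 and Bcl6 were again 3 of the 10 direct targets (exact p = 0.00713, adjusted p = 0.0926), and 4 of 10 with Pim1 when 50 kb upstream was allowed (adjusted p = 0.0181). The Tat region was hypox-only (5.58 ± 1.19). The total of 897 was the largest of 35 divisions (next 297, exact one-sided p = 0.0286, the smallest possible). Within codes it was the largest of 15 divisions, where the smallest exact p is 0.0667. GH-only regions numbered 1076 without hypox female pool 2, and hypox-only regions 388 without 90 min pool 1 and 739 without hypox female pool 1, where they outnumbered the 667 GH-only regions. At 240 min, 23.3% of the 660 were called in both pools, 23.9% in 1 and 52.7% in neither, against 22.3 and 25% for both and neither in the chance model.

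The STAT consensus was frequent in regions called after GH and not before. It was present in 46.0% of GH-only regions at 30 min (exact 95% interval 43.6 to 48.5), 45.0% at 90 min and 30.6% at 240 min, compared with 8.22% of regions called in all 14 libraries. The share was 57.4% for 30 and 90 min without hypox calls and 66.2% for all 6 GH libraries. Against matched regions the odds ratios were 10.03 at 30 min (adjusted p = 1.13e-98, exact test), 9.60 at 90 min (7.07e-105), 5.49 at 240 min (1.37e-30) and 23.6 in the strictest class (4.44e-27). The control with a gap of 4 bases was also above matched regions at 30 min (1.94, adjusted p = 0.000306, exact test) and 90 min (2.07, adjusted p = 9.97e-06), at a far lower odds ratio. Hypox-only regions at 30 and 90 min held the consensus less often than matched regions, in 2.91% (0.381, exact test, adjusted p = 4.56e-08) and 2.97% (0.405, adjusted p = 1.61e-06). Those at 240 min (4.61%, 0.818, adjusted p = 0.588, exact test) and in females (6.99%, 0.788, adjusted p = 1.0) did not pass. In intact females the share among intact-only regions was 11.02% (matched odds ratio 1.55, exact test, adjusted p = 0.00728). By the same exact test, that call ended when 100 bp were searched, at an odds ratio of 1.555 (adjusted p = 0.0822). It also ended with equal lists (odds ratio 1.273, adjusted p = 0.485, exact test) and without hypox pool 1 (1.432, adjusted p = 0.0651).

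**Figure D5:**
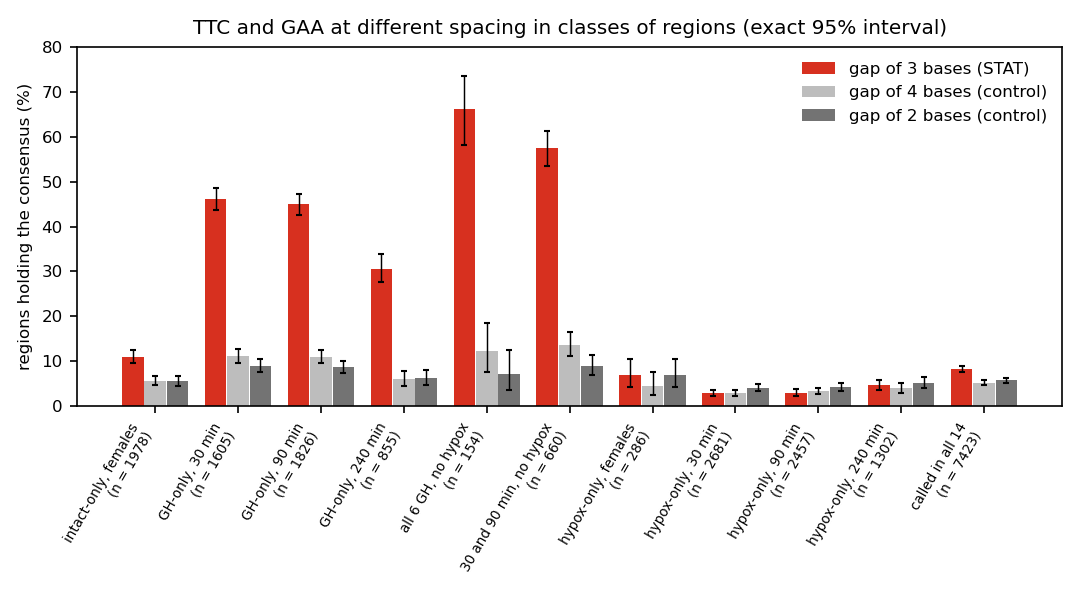
Percent of regions holding TTC and GAA with a gap of 3 bases (the STAT consensus, red) or of 4 or 2 bases (controls, grey), in 11 classes of regions, with exact 95% intervals. The red bars of the GH-only classes lie between 30.6 and 66.2%, and those of the hypox-only classes between 2.91 and 6.99%.

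Among other sequences, by Fisher's exact test, the HNF6/CUX site was more frequent in intact-only regions (matched odds ratio 2.14, adjusted p = 0.00728) and in GH-only regions at 240 min (2.83, adjusted p = 0.0477), and both calls ended when 100 bp were searched, at odds ratios of 1.955 and 2.738. The first ended without intact pool 2 (adjusted p = 0.0575, exact test), 3 (0.0602) or 4 (0.152) or hypox pool 1 (0.0739), and the second without 240 min pool 1 (0.099) or hypox male pool 2 (0.856). With single libraries left out, the odds ratios were 1.53 to 2.098 for the first and 1.224 to 2.07 for the second. AP-1 was more frequent in GH-only regions at 240 min (2.20, adjusted p = 0.00478, exact test). Against matched regions, FOXA was less frequent in GH-only regions at 30 min (0.703, exact test, adjusted p = 0.0179), 90 min (0.570, 1.52e-05) and 240 min (0.661, 0.0477). Its share did not pass a direct test against hypox-only regions at any time (odds ratios 1.059, 1.072 and 1.300, smallest exact p = 0.0783). C/EBP was more frequent in GH-only than hypox-only regions at 30 min (20.25 against 13.58%, adjusted p = 4.9e-08, exact test), 90 min (20.7 against 15.38%, 3.02e-05) and 240 min (20.94 against 11.29%, 1.46e-08). These regions were not matched on width or GC, and against matched regions the C/EBP odds ratios of GH-only regions were 0.927, 0.922 and 0.938. Against matched regions, NF-Y was less frequent in GH-only regions at 30 min (0.544, exact test, adjusted p = 1.2e-06) and 90 min (0.577, 4.61e-06), and in hypox-only regions at 30 min (0.541), 90 min (0.596) and 240 min (0.537).

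Regions that intact females had and hypox females lacked were then looked up in males. Of the 1978 intact-only regions, 20.8% were called in both untreated hypox male pools (exact 95% interval 19.0 to 22.6), 17.4% in both pools at 30 min, 15.2% at 90 min and 19.5% at 240 min. Of the 286 hypox-only regions, the shares were 52.1% in untreated males and 27.6, 38.1 and 27.6% at the 3 times. The intact-only shares were lower than the hypox-only shares in each group across regions (odds ratios 0.241, 0.554, 0.291 and 0.633, the largest exact two-sided p = 0.00216), and regions are not replicates of animals. With equal lists, intact-only shares were 16.3% in untreated males and 21.1, 13.6 and 27.4% after GH, so that the share in untreated males was no longer above those at 30 and 240 min. The hypox-only shares were then 51.25% in untreated males and 26.98, 42.58 and 28.93% after GH, and the difference at 240 min no longer passed (odds ratio 0.929, exact two-sided p = 0.464). Without hypox female pool 2 the intact-only shares were 43.97% in untreated males and 36.16, 34.6 and 39.42% after GH. Among individual regions, those at Cyp3a44, Cyp3a16, Cyp17a1 and Cux2 and the intact-only Socs2 intron stayed without a call in males at every time. The region near Igf2, by contrast, was called in all 6 GH libraries.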

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

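In this part, the tests of sequence shares between times, of list length, library code, other divisions and single pools were chosen only after the result was seen, as was the class of 30 and 90 min without hypox calls on which 2 of the STAT tests rest, although the bounds of the STAT tests were set before their values were known.

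GH-only regions at 240 min that were not shared with an earlier time differed in sequence from those of that time. A difference between time points in shares of GH-only regions drew attention to them. Regions shared by the times compared were left out, the test was Fisher's exact test, two-sided, and adjustment was over 39 tests. The STAT consensus was in 43.6% of 1203 regions at 30 min and 10.6% of 453 at 240 min (adjusted p = 9.2e-40, exact), and in 43.2% of 1381 at 90 min against 9.0% of 410 at 240 min (3.99e-41). The HNF6/CUX site was in 1.2 against 4.6% for 30 and 240 min (adjusted p = 0.000489, exact) and in 1.4 against 5.1% for 90 and 240 min (0.000489). AP-1 was in 5.5 against 12.8% (adjusted p = 2.19e-05, exact) and in 6.2 against 11.2% (0.00529). NF-Y was in 13 against 19.9% (adjusted p = 0.00407, exact) and in 13.9 against 21.0% (0.00448). Between 30 and 90 min no sequence of 13 passed. The whole GH-only class at 240 min held 855 regions against 511 in the chance model, and 30.6% of the 855 held the STAT consensus. It shared 402 regions with 30 min (88 in the chance model) and 445 with 90 min (100). The regions left at 240 min were therefore about as many as the chance model gives, so their shares need not describe a response to GH. The 3 times share the untreated male libraries, and regions are not replicates of animals.

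For the 660 regions called at 30 and 90 min and in no untreated hypox library, the library code as the whole source is argued against, since both hypox females, which carry the code of the GH libraries, had 3.3% of the 1120 regions that the males lacked, and the total against females alone was 1406 (highest of the 14 other divisions 819). Of the 1120, 58.9% were in neither hypox female pool and the rest in at least 1, for which the code stays open, and sex differs in this comparison. List length is argued against by 706 regions with equal lists. Chance division can be excluded for the planned count of 154 regions of all 6 GH libraries (1 of 210, highest other 101, and within codes 1 of 28). For the total of 897, 1 of 35 divisions was as large (highest other 297). That comparison was added after the data were seen, so its test cannot exclude chance. Within codes the 15 divisions are too few for the total of 897 (highest other 297), and chance is not excluded for the total of 209 of all 6 GH libraries, which 3 of 210 divisions reached (highest other 415, which follows time) and 2 of 28 within codes (highest other 215). A candidate explanation that stays open, as a hypothesis, is STAT binding after GH, with a matched odds ratio of 14.492 for the consensus, against 2.34 and 1.59 for the controls with gaps of 4 and 2 bases.

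Intact-only regions outnumbered hypox-only regions in females, 1978 against 286, but not without hypox pool 1 (2248 against 2302). The code is argued against as the source, since the ratio within G92 was 4.46. List length stays open, since with equal lists the ratio was 1.29 (1192 against 923). STAT binding under the pituitary's GH may contribute, with a matched odds ratio of 1.553, but that odds ratio was 1.273 with equal lists (adjusted p = 0.485, exact). The 15 divisions are too few for a share under 0.05, with a real total of 2264 and a highest other of 1590.

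Fewer regions set 240 min apart from untreated males than 30 or 90 min, with totals of 2157, 4286 and 4283. Unlike pools at 240 min could account for this: single pools gave totals of 6051 and 5881 at 240 min, 7809 and 6562 at 30 min and 7303 and 7040 at 90 min. The 240 min pools leaned apart, with 4555 GH-only and 1496 hypox-only regions for pool 1, and 1165 and 4716 for pool 2. Closing of STAT regions by 240 min cannot be told apart from this: the consensus was in 56.6% of 348 regions absent at 240 min and 66.2% of 154 present in both pools (odds ratio 0.666, 95% interval 0.438 to 1.0, exact two-sided p = 0.0486). The bound set beforehand against closing was met by this odds ratio and p, but not by more than the spread, since the interval reaches 1.0, and leaving closing open on that ground was decided after the value was seen.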

How the results depend on the processing

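In this part, the tests chosen only after the result was seen are all those of the comparison of 30 and 90 min with the 4 untreated hypox libraries, the sequence results with equal lists, the sequence, list and share results with single libraries left out, similarity under the stricter threshold and the wider coverage, the divisions within pool numbers or codes, and the joint omission of intact pool 3 and hypox female pool 1. The odds ratios of the sequences listed below stayed on their side of 1 in every setting run. Which side of a comparison held more regions did change. With equal lists, and with best peaks set against full lists, the GH-only side became the larger at 30, 90 and 240 min and for any GH, and the 30-only side against 240 min. With the combined lists the hypox-only side became the larger for all 6 GH libraries against 4 hypox libraries. Without hypox female pool 1 the larger side became the hypox-only side in females, the female-only side for sex, and the hypox-only side for all 6 GH libraries and for 30 and 90 min against the 4 hypox libraries. The GH-only side became the larger at 90 min without 90 min pool 2, and at 240 min without 240 min pool 2, and the 30-only side against 240 min without 30 min pool 2 or 240 min pool 1. No test set one side's count against the other's. Coverage of at least 50% of a region kept all 18 counts within 1.5 times. A −log10 p of at least 10 kept 17, with 123 female-only regions in hypox mice. On average, pools of the same group stayed more alike with equal lists (exact one-sided p = 0.00106), under the stricter threshold (0.00741) and with 50% coverage (0.0106). The replicate block keeps the number of libraries of each pool number per side. The labels do not say that pool numbers pair samples, and differences between pools 1 and 2 correlated across regions at -0.103 to 0.054 between groups (15 pairs of groups). With this block the exact one-sided p was 0.0625 for the total of any GH and 0.0556 for 30 and 90 min against 4 hypox libraries, each the smallest that the 16 and 18 divisions allow, and it changed no other call. With the code as a block it was 0.0714 for the total of all 6 GH libraries (2 of 28 divisions) and 0.0667 for 30 and 90 min (1 of 15, the smallest possible, by exact enumeration). The planned count test, with its other scaling and its filter on low counts, was not run because the files used held peak lists, and similarity was not run without single libraries, since each pair needs both. Libraries differ in depth and in list length, which limits what absence of a call means, and the cause of the moves below was not tested except where stated.

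With each list limited to its 17691 best peaks, 12 of 18 counts stayed within 1.5 times. The others were 1192 intact-only and 923 hypox-only regions in females, 751 male-only and 489 female-only regions in hypox mice, 1424 hypox-only regions at 30 min and 388 for any GH. Intact-only shares became 16.28% in untreated males and 21.14, 13.59 and 27.43% at 30, 90 and 240 min. At 240 min the odds ratio of intact-only against hypox-only regions was 0.929, no longer past the threshold. With 50% coverage the shares after GH became 14.04, 12.5 and 16.72%. Within code G92, hypox-only regions in females numbered 639. Without intact pool 3 and hypox female pool 1, intact-only and hypox-only regions numbered 3010 and 2454.

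A call among the best peaks of one side and absence from the full lists of the other is the stricter rule, so counts were lower by construction. They were 721 and 153 for intact-only and hypox-only regions in females, 252 and 85 for male-only and female-only regions, 687 for hypox-only regions at 30 min, 1123 and 734 for GH-only and hypox-only regions at 90 min, 403 and 243 at 240 min, and 617 and 511 for 30-only and 240-only regions. For any GH they were 188 and 97, for all 6 GH libraries against 4 hypox libraries 70 and 6, and for 30 and 90 min against those 408 and 69. The authors' combined lists ask for 1 list per group, so counts were higher. In the same order they were 15519 and 1513, 6060 and 2486, 4135 and 7321 at 30 min, 4609 and 6665 at 90 min, 3644 and 5333 at 240 min, 3997 and 5494, 1230 and 3091, 731 and 840, and 2060 and 1782.

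Leaving out 1 library raises counts by construction. The ranges were 2024 to 4419 intact-only and 319 to 2302 hypox-only regions in females, and 1962 to 5032 male-only and 378 to 3290 female-only regions. GH-only and hypox-only regions ranged from 1924 to 3501 and 4070 to 6032 at 30 min, 2188 to 4208 and 3095 to 5430 at 90 min, and 1165 to 4555 and 1496 to 4716 at 240 min. The 30-only and 240-only regions ranged from 1224 to 2967 and 1633 to 6589. Any GH gave 366 to 631 and 672 to 2413, all 6 GH libraries against 4 hypox libraries 154 to 338 and 60 to 243, and 30 and 90 min against those 667 to 1076 and 271 to 739. Intact-only shares ranged from 15.41 to 43.97% in untreated males, 14.9 to 36.16% at 30 min, 13.62 to 34.6% at 90 min and 15.08 to 39.42% at 240 min.

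The odds ratios of the STAT consensus in GH-only regions and in hypox-only regions at 30 and 90 min kept their side of the threshold in every setting run. In intact-only regions the STAT odds ratio was 1.555 with 100 bp searched and 1.273 with equal lists, neither past the threshold, and 1.432 to 1.843 with single libraries left out. HNF6/CUX in intact-only regions gave 1.955 and 2.069, also not past it, and 1.53 to 2.098. HNF6/CUX in GH-only regions at 240 min gave 2.738 and 1.826, likewise, and 1.224 to 2.07. STAT in hypox-only regions at 240 min ranged from 0.706 to 0.931 and passed without 240 min pool 1 (0.754, exact test, adjusted p = 0.039). The number of list tests past the threshold was 1 with 10 kb upstream, 0 with 2 kb, 5 with 50 kb and 0 to 4 with single libraries left out: 0 without 240 min pool 2, 2 without intact female pool 2 or 3 or either hypox female pool, 3 without hypox male pool 1 and 4 without hypox male pool 2. The 5 were glucocorticoid-responsive genes at 30 min, at 90 min and for any GH, male-biased genes at 90 min (7 of 19, adjusted p = 0.0436, exact test), and direct GH targets at 30 and 90 min against the 4 hypox libraries.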

Other observations

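In this part, the classes by time and the tests on them were chosen only after the result was seen, as was the division of intact-only regions by the STAT consensus, and the test of that division was set before its result was known.

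A late set of 189 regions was called in both 240 min pools and in no untreated hypox male, 30 min or 90 min library. No chance-model count and no division test was made for this set. It is part of the GH-only class at 240 min, which held 855 regions against 511 in the chance model. The highest folds were in an intron of Dio1 (4: 106975233-106975820, mm9, 9.0 ± 2.18, n = 2), an intron of Tbxas1, the thromboxane synthase gene (6: 38879016-38879591, 8.8), and the promoter of Havcr1 (11: 46548032-46548783, 8.74). All 3 were called in the 4 intact females and 1 hypox female, and Tbxas1 and Havcr1 were chosen after their values were seen. The STAT consensus was in 4.2% of the late set, and against regions called in all 14 libraries the odds ratio was 0.494 (exact two-sided p = 0.0572). Without a call in hypox females as well, 141 regions remained, and 3.5% of them held the consensus (odds ratio against all 14 libraries 0.411, exact two-sided p = 0.0424). With these same controls, it was in 56.6% of the 348 regions of 30 and 90 min absent at 240 min (141 against 348, odds ratio 0.0283, exact two-sided p = 1.62e-32). HNF6/CUX was in 6.9% of the late set, and 25.9% of the set was called in all 4 intact females.

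Fate at 240 min and calls in intact females went side by side. Of the 348 regions of 30 and 90 min absent at 240 min, 4.6% were called in all 4 intact females and 59.5% in none. Of the 158 called in 1 of the 240 min pools, the shares were 21.5 and 22.2%, and of the 154 called in all 6 GH libraries 39.6 and 15.6%. The difference was not tested, and no chance-model shares were computed for it. In the chance model a region called in more libraries has a higher chance of a call in each. These shares therefore cannot separate lasting calls from ease of detection. The Ces2b region belonged to the middle set and was called in no intact female, whereas the Acsm2 region and the 1 located 136.8 kb downstream of the start of Rnf144b were called in all 6 GH libraries and all 4 intact females.

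A hypothesis is that some regions open in intact females and not in hypox females open after GH in males through STAT binding. Of the 218 intact-only regions with the consensus, 12.4% were called in both untreated male pools and 50.5% in both 30 min pools, with 48.2 and 30.7% at 90 and 240 min. Here 96 regions were called at 30 min only and 13 in untreated males only (exact two-sided p = 8.3e-17). Of the 1760 without the consensus, 21.8% were called in untreated males and 13.4% at 30 min (139 against 288, exact two-sided p = 4.63e-13). The result is consistent with the hypothesis for these libraries, in which GH and library code cannot be separated in males, and regions are not replicates of animals.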
